A study of Mus musculus with 160 samples.

How the data were processed

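RNA was measured in 160 single cells, 82 from young and 78 from old mice, each listed as a sample of its own. Per the labels' protocols, cells were captured on microfluidic chips (Fluidigm C1) with 96 wells counted for each age, and amplified with the SMARTer chemistry. Spike RNAs were added per the same protocol and were not used here. Wells with no cell, several cells or a shrunken cell were set aside by microscopy, leaving 83 young and 79 old wells, 1 more of each than analysed here. No doublet caller was run, because doublets were removed by eye and a chip holds few cells.

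The values are FPKM (fragment numbers scaled by transcript length and by the mapped fragments of the cell) as deposited by the authors in 1 table of genes by cells. The submitters' processing notes name Cufflinks 2.1.1 and the mouse genome build mm9. How reads shared between genes were divided, the filters and the read numbers are not given in the sources used here. FPKM carry no read counts, so no count model was used and the depth is unknown. The table holds 31199 rows, of which 7751 carry no gene name and were left out of all comparisons. The share of FPKM on them is given in the closing section. The 23448 named rows hold 22866 distinct names. Rows of the 468 names found more than once were summed, a choice made after the file was seen. A further 356 rows join several gene symbols, so such a value cannot be given to 1 of them, and 27 names had been turned into dates. An annotation of another build served only to count names: 21330 matched a symbol. No coordinates are given. No 2 cells had identical columns.

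An FPKM of exactly 0 can be a failed estimate. Gapdh, which nearly all cells use, was listed at 0 in 91 of 160 cells and Col1a1 in 112, while Actb and B2m were listed above 1 in 160. A gene missing from a cell is therefore described as not listed at 1 FPKM, and the limits given for shares of 0 concern cells listed at that level, not cells that express the gene. High values can also rest on few fragments: 84 named values in 21 cells exceeded 50000 FPKM.

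Groups came from the age in the sample labels. Both ages number their cells from 1, but the numbers are names and pair nothing. The main measure, fixed before the data were examined, was log2 of the ratio of mean FPKM, old over young, with a pseudocount of 1 added to each mean, which understates the ratio of low genes. A gene counted as measured at a mean of 1 FPKM or more in either age (7196 genes), and as listed in a cell at 1 FPKM. For 37 gene lists fixed beforehand, the median log2 ratio of measured members was placed among 10000 random lists of equal size, matched on mean FPKM in 20 bins. A list stands apart when it lies outside the middle 95%, which describes these cells and is not a test. Lists needed 5 measured members. The share of cells for 1 gene fixed beforehand is not reported here.

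Named genes followed a rule fixed beforehand: a mean of 10 FPKM in an age and 1 FPKM in 25% of its cells, the same sign of the ratio of means, of the difference of mean log2(FPKM + 1) and of the difference in share, then the 12 highest and 12 lowest ratios, skipping predicted, ribosomal protein and small RNA genes. Of 973 genes past the first filter, 595 had the same sign. Since the ratios proved to be set by single cells, the same filter was also ranked by the difference of mean log2(FPKM + 1). That measure was planned as an alternative, but ranking by it was decided after the values were seen. For each list the rule takes its highest and lowest ratio at a mean of 5 FPKM and its 2 highest means. The report shows some of these, and the members and genes shown were picked after their values were seen.

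Clusters came from log2(FPKM + 1) of the 1000 most variable genes among those listed in 10% of cells, 10 principal components and Ward linkage, with the number of clusters from 2 to 6 taken by silhouette (0.284 for 2). Leading genes are the 10 with the highest ratio of means among genes listed in 50% of a cluster's cells.

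The steps were tested on simulated data: groups of 82 and 78 cells were resampled from young cells, leaving out cells of extreme summed FPKM, and 200 genes were changed in the simulated old cells. Over 6108 genes, true log2 changes of 2 and -2 came back from the ratio of means as medians of 1.96 and -1.90, and changes of 1 and -1 as 0.96 and -0.80. The difference of mean log2 gave 1.00, -0.87, 0.49 and -0.36 for the same changes, because cells at 0 do not change, so its sizes are smaller than the true ones. Of 100 lists of unchanged genes, 3 stood apart by the ratio and 6 by the log difference. These lists were drawn at random, as were the lists they were set against, so few standing apart was built in. Lists of genes that vary together were not simulated. Because extreme cells were left out, the simulation does not show how the ratio behaves with them. Clustering was tested with 100 genes raised in a random 80 of 160 cells, on 3 backgrounds. Each value was multiplied by 100 and a fixed FPKM was added, so cells at 0 rose too. Recovery of so large a change does not show whether smaller differences between cells would be found. A first simulation, on cells resampled with replacement, returned 6 clusters, of whose cells 135 of 160 lay with the majority of their kind, and forced to 2 clusters it placed 101 of 160. 2 simulations added after that failure, on each real cell used once and on genes shuffled over cells, returned 2 clusters with 160 of 160 cells in place. The clustering itself was left as fixed, and it did not recover the groups where cells were duplicated.

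Alternatives fixed beforehand were other detection levels, pseudocounts of 0.1 and 5, rescaling every cell to the same sum, the difference of mean log2, means without the highest and lowest 5% of cells, other gene filters, and sets of cells inside the gate by RNA, within the interquartile range of genes detected, or above 50% of the median gene number of their age. Inside the gate by RNA meant Lepr or Pdgfra listed and neither Ptprc nor Pecam1, which held for 151 of 160 cells. This is less strict than the sort, which asked for both receptors. Alternatives added after seeing the data were leaving out cells of summed FPKM over 3 times the median, the highest in place of the sum of rows that share a name, and mean log2 in each set of cells. The lists were thus read under 17 settings, the main one, 10 fixed beforehand and 6 added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.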

Results

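Single stromal cells were sorted from the bone marrow of young and old C57BL/6J mice and their RNA was sequenced cell by cell, 82 cells from young and 78 from old mice. The sort kept cells that carried the leptin receptor and the platelet-derived growth factor receptor alpha (CD140a) and lacked CD45, Ter119 and CD31, the surface marks of blood, red and endothelial cells. The sample labels give ages of 9 weeks and 24 months, and the protocol text gives 10 weeks and 2 years. No animal is named for any cell, so each age counts as 1 sample, differences between ages have no replicate check, and no test was made. Intervals below are exact (Clopper-Pearson) 95% intervals of shares of cells and cover counting error only. For a share of 0 the text gives the share that 3 cells of the group would make, which is smaller than the exact upper limit (4.40% for 0 of 82 and 4.62% for 0 of 78 cells). Values are FPKM, the number of reads was not given in the sources used here, and the depth per cell is unknown. Young cells had a median of 1114.5 named genes at an FPKM of 1 or more (quartiles 666.5 and 1371 over cells), and old cells had 1160 (570.3 and 1379). Counting any FPKM above 0 turned this order, with medians of 2160.5 and 2019 genes. The range at 1 FPKM was 129 to 2129 genes in young and 193 to 2779 in old cells.

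The 2 ages differed in sex-linked RNA. Xist, the RNA that coats the inactive X chromosome in female cells, was at an FPKM of 1 or more in 54 of 78 old cells (69.2%, interval 57.8 to 79.2) and in 0 of 82 young cells, which allows a share of up to 3.66%. At least 1 of the 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty was at that level in 34 of 82 young cells (41.5%, interval 30.7 to 52.9) and in 0 of 78 old cells, which allows up to 3.85%. No cell had both. In 48 young and 24 old cells neither was seen. The labels give no sex, and the protocol counts 96 wells for each age, so the ages were captured in separate sets of wells, and age, sex-linked RNA and capture vary together in every comparison of the ages that follows.

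Most cells of both ages carried the RNA of the gated receptor Lepr and of marrow niche stroma, whereas Pdgfra was listed in a minority. Cxcl12, the chemokine that retains blood stem cells, was at an FPKM of 1 or more in 82 of 82 young and 77 of 78 old cells, with medians of 966 and 823 FPKM. Lepr, the gated receptor, was found in 95.1% of young (interval 88.0 to 98.7) and 91.0% of old cells (82.4 to 96.3). Adipoq, the adipocyte hormone adiponectin, was found in 95.1% and 87.2%, and Kitl, the stem cell factor, in 95.1% (88.0 to 98.7) of young and 79.5% (68.8 to 87.8) of old cells. Pdgfra, the other gated receptor, was found in only 34.1% and 38.5% of cells. Ptprc (CD45) and Pecam1 (CD31) were in 0 cells of either age. No cell held 3 or more members of the hematopoietic, erythroid, endothelial, megakaryocyte, Schwann cell, pericyte and smooth muscle or chondrogenic marker lists. At least 3 osteogenic members were listed in 80 young and 71 old cells, at least 3 adipogenic members in 72 and 60, and at least 3 fibroblast members in 18 young (22%, interval 13.6 to 32.5) and 30 old cells (38.5%, interval 27.7 to 50.2). Ibsp, a bone matrix protein, was in 98.8% and 88.5% of cells, whereas Sp7, the osteoblast transcription factor, was in 4 young and 4 old cells, Alpl in 7 and 5, Sox9 in 3 and 7, and Bglap in 0 and 1. The proliferation genes Mki67 and Top2a were in 0 cells, and at least 3 S phase genes were listed in 3 young and 4 old cells.

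The p53 question of the series title was followed in the p53 genes of these cells. Cdkn1a, the p53 target that arrests the cell cycle, was at an FPKM of 1 or more in 23 of 82 young cells (28%, interval 18.7 to 39.1) and in 4 of 78 old cells (5.13%, interval 1.41 to 12.6). Trp53 itself was in 7 young and 8 old cells, Mdm2, which encodes the ligase that degrades p53, in 12 and 12, and Cdkn2a in 0 and 0. The 21 measured p53 targets had a median log2 ratio of means of 0.12, with 12 higher in old and 9 higher in young cells, at the 55.9th percentile of 10000 random lists matched on mean FPKM. Within the list the log2 ratio ran from -3.03 for Tnfrsf10b to 3.04 for Ak1. However, 1 cell held 89.3% of the summed FPKM of Tnfrsf10b and 1 cell 54.2% of that of Ak1. Their differences of mean log2(FPKM + 1), old minus young, were -0.12 and 0.65. The 13 measured p53 network and sarcoma genes had a median of -0.24 (27.4th percentile, 5 higher in old cells). Neither list lay outside the middle 95% of random lists. In cells within the interquartile range of genes detected the p53 targets had a median of 1.09 and the 97.8th percentile, outside that range. After rescaling every cell to the same sum their median was -0.12, at the 34.2th percentile. By mean log2, in all cells and in each set of cells, it ran from 0.02 to 0.08 and stayed inside the random range.

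The gene list with the highest percentile among random lists was the unfolded protein response, the chaperones and sensors of the endoplasmic reticulum. Of its 20 measured members 14 had a higher mean in old and 6 in young cells, and the median log2 ratio was 1.08, at the 99.8th percentile of random lists. Cells with 3 or more fibroblast members were also more frequent among old (38.5%) than young cells (22%). Hspa5, the chaperone BiP, had a mean of 38.6 FPKM in young and 115 in old cells, with 28.9% of its summed FPKM in 1 cell, and means of 24.4 and 61.4 without the highest and lowest 5% of cells. It was listed in 57.3% of young (interval 45.9 to 68.2) and 76.9% of old cells (66 to 85.7). Hsp90b1, the chaperone Grp94, was listed in 62.2% (50.8 to 72.7) and 82.1% (71.7 to 89.8). Canx, the lectin chaperone calnexin, had the lowest log2 ratio of the list, -4.97, but 1 cell held 95.2% of its summed FPKM and its mean log2(FPKM + 1) was 3.77 in young and 4.46 in old cells. With cells under the 50% mark of the median gene number of their age left out, the list median was 0.70, at the 97.4th percentile and no longer outside the middle 95%, whereas the difference of mean log2(FPKM + 1) in the same cells was 0.46, at the 99.99th. The sex-linked list was the only other list outside it among 27 lists with 5 or more measured members, where randomly drawn lists would give 1.35. That number leaves out that members of a real list can vary together. Its 4 Y-linked members were higher in young cells and Xist in old cells.

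**Figure D1:**
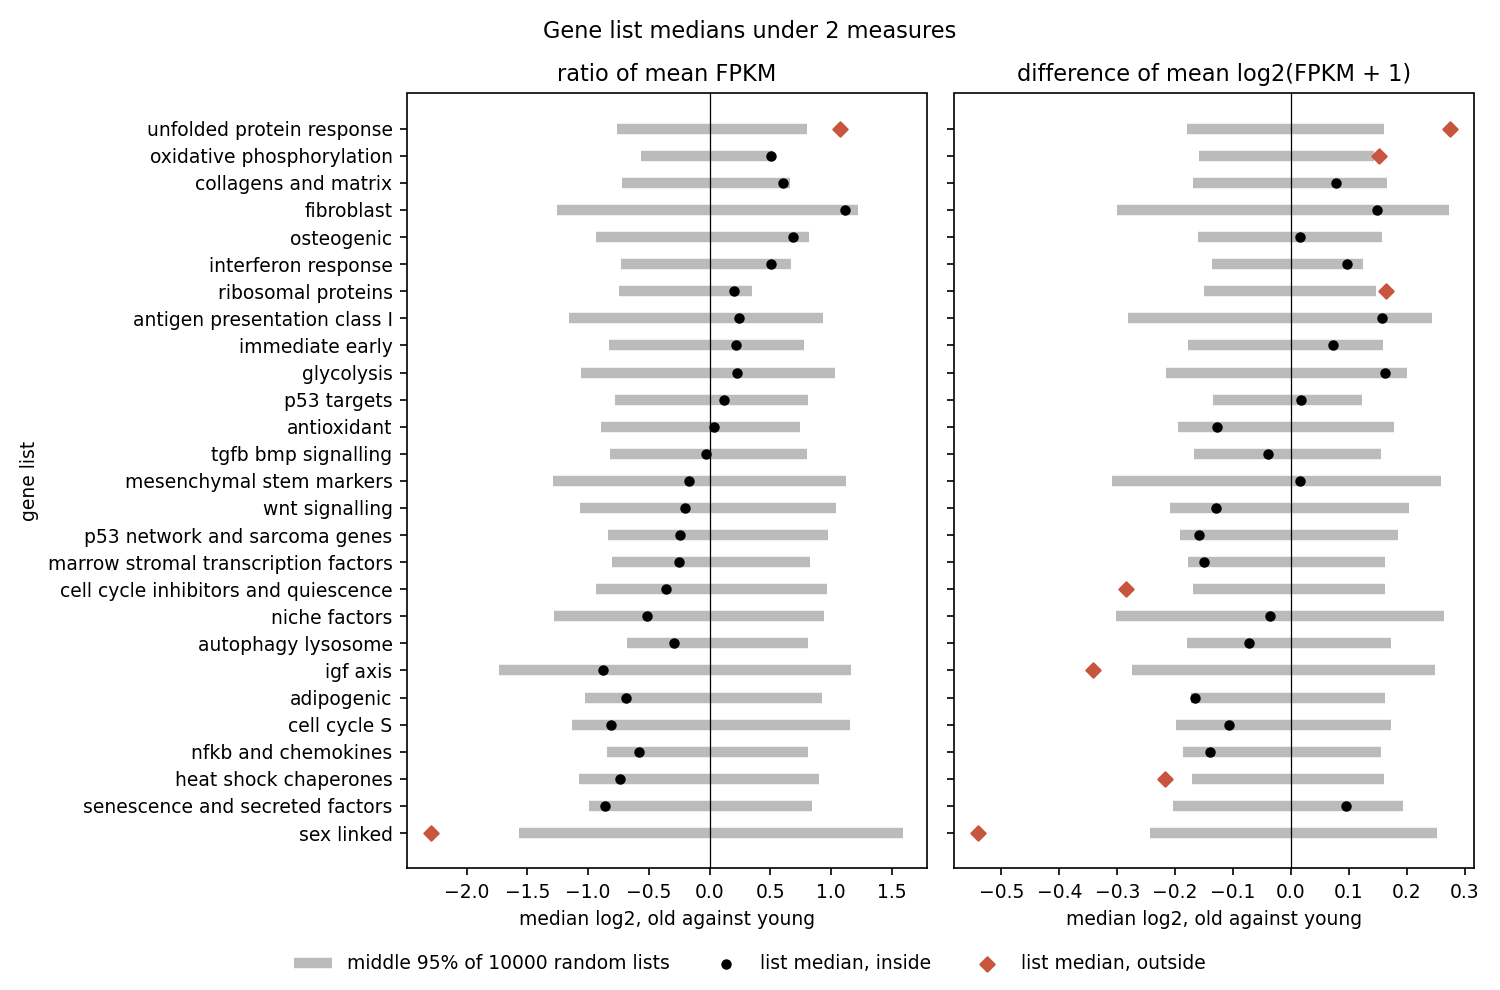
Median log2 of old against young cells for the 27 lists with 5 or more measured members, by the ratio of mean FPKM (left) and by the difference of mean log2(FPKM + 1) (right), each on its own linear axis. Grey bars span the middle 95% of 10000 matched random lists and red diamonds mark medians outside it: 2 lists on the left, and 7 on the right, where the unfolded protein response stood at 0.27.

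The other lists lay inside the middle 95% of random lists by the ratio of means. Toward old cells lay oxidative phosphorylation (median log2 ratio 0.50, 97.2th percentile, 24 of 40 members higher in old cells), collagens and matrix (0.60, 96.3th, 17 of 28), fibroblast genes (1.12, 95.7th, 5 of 7), osteogenic genes (0.68, 95.1th, 11 of 19), the interferon response (0.51, 93.0th, 18 of 28) and ribosomal proteins (0.20, 89.2th, 38 of 70). Toward young cells lay senescence and secreted factors (-0.86, 4.26th, 10 of 17 members higher in young cells), heat shock chaperones (-0.74, 7.53th, 10 of 14), NF-kB targets and chemokines (-0.58, 8.74th, 13 of 18), S phase genes (-0.81, 10.3th, 5 of 7), adipogenic genes (-0.69, 10.3th, 9 of 14) and the IGF axis (-0.87, 13th, 6 of 9). Closer to the middle, with medians below 0, lay autophagy and lysosome (-0.30, 14.5th percentile), niche factors (-0.52, 17th) and cell cycle inhibitors and quiescence (-0.36, 21.3th). Marrow stromal transcription factors (-0.25, 23.7th), Wnt signalling (-0.21, 33.8th) and mesenchymal stem markers (-0.17, 37.7th) lay there too. TGF-beta and BMP signalling (-0.03, 45.3th), antioxidant genes (0.03, 53.8th), glycolysis (0.23, 63.7th), immediate early genes (0.22, 68.6th) and class I antigen presentation (0.24, 68.6th) lay near the middle. By the difference of mean log2(FPKM + 1), which weighs each cell alike, 3 lists lay above the random range and 4 below. Oxidative phosphorylation (0.15, 98.3th percentile) and ribosomal proteins (0.16, 98.6th) joined the unfolded protein response. Cell cycle inhibitors and quiescence (-0.29, 0.01th), heat shock chaperones (-0.22, 0.63th) and the IGF axis (-0.34, 0.87th) joined the sex-linked list. The senescence list changed sign, with a median of 0.09 at the 84.6th percentile. Other lists placed toward old or young cells above also took both signs over the 17 settings. These were osteogenic genes (medians from -0.74 to 0.74), adipogenic genes (-1.15 to 0.29), NF-kB targets and chemokines (-0.75 to 0.05) and S phase genes (-1.41 to 0.07). Niche factors (-1.38 to 0.25), Wnt signalling (-0.64 to 0.68) and marrow stromal transcription factors (-0.49 to 0.13) did so too. The same held for mesenchymal stem markers (-0.33 to 0.11) and autophagy and lysosome (-0.32 to 0.06).

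Lists with under 5 measured members gave values only. Their median log2 ratios were -1.12 for the 2 gate genes, -0.64 for 2 chondrogenic, -1.03 for 3 pericyte and smooth muscle, -1.23 for 2 Schwann cell, 1.40 for 3 hematopoietic, 0.63 for 2 erythroid genes and 1.83 for the 1 endothelial gene. No member of the gate-negative, megakaryocyte and G2/M lists reached a mean of 1 FPKM in either age.

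Genes ranked by the ratio of mean FPKM, the ranking fixed before the data were examined, were set by single cells. Among the 12 lowest ratios were Col4a2, a basement membrane collagen (mean 2479 FPKM in young and 4.86 in old cells), Lmo7 (1183 and 2.76), Ccar1, Cox7b, Eef2, Ltbp1, Copb1, Asph, Atp5g2, Adh1, Col1a2 and Grem1, and the log2 ratios ran from -8.73 for Col4a2 to -5.41 for Grem1. The 12 highest were Myl6 (listed jointly with Myl6b, mean 61 and 17100 FPKM), Cox6b1 (42.4 and 10625), Akap12, Atp5g1, Sdc4, Psmb8, Hsp90b1, Fbln1, Pcbp1, Snrnp70, Jag1 and Tjp1, with log2 ratios from 8.11 to 3.79. In 24 of these 24 genes 1 cell held over 50% of the FPKM summed over both ages: 99.6% for Col4a2, 99.1% for Myl6 and 98.9% for Cox6b1. Col4a2 was listed in 28 young and 21 old cells, and Myl6 in 40 and 39.

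The same filter ranked by the difference of mean log2(FPKM + 1), a ranking chosen after these values were seen, gave genes carried by many cells. In 2 of its 24 genes, Col1a2 and Hsp90b1, 1 cell held over 50% of the FPKM, and these 2 were named by both rankings. Lowest in old cells was Spp1, the secreted matrix protein osteopontin, listed in 82.9% of young (interval 73 to 90.3) and 32.1% of old cells (21.9 to 43.6), with mean log2 values of 5.54 and 2.25. Serpina3n and Serpina3m, protease inhibitors listed as 1 joint row, were in 63.4% of young and 5.13% of old cells, Cldn10, a tight junction claudin, in 56.1% and 10.3%, and Scara5, a scavenger receptor, in 43.9% and 3.85%. Vcam1, the vascular cell adhesion molecule, was listed in 92.7% (84.8 to 97.3) and 67.9% (56.4 to 78.1), Sepp1, which encodes the selenium carrier selenoprotein P, in 90.2% and 60.3%, and Lbp, which encodes lipopolysaccharide-binding protein, in 64.6% and 20.5%. Fmo2, Slc6a6, Col1a2, Dpep1 and Fgfr2 completed the 12, with differences of mean log2 from -2.04 to -1.87.

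Highest in old cells by that ranking, after Xist, was Aldh1a2, an enzyme that makes retinoic acid, listed in 18.3% of young (interval 10.6 to 28.4) and 61.5% of old cells (49.8 to 72.3). The complement component C3 was in 19.5% (11.6 to 29.7) and 67.9% (56.4 to 78.1). The matrix genes Col6a1 (46.3% and 74.4%), Dcn, which encodes decorin (41.5% and 66.7%), Efemp1 (11% and 46.2%) and Mgp, matrix Gla protein (81.7% and 92.3%) were also higher in old cells, as were Phex, a bone endopeptidase (17.1% and 53.8%), the noncoding Snhg11 (4.88% and 44.9%) and Sp100 (1.22% and 34.6%). Hsp90b1 and Hspa5 completed the 12. In this comparison Xist was listed in 54 of 78 old cells and Y-linked RNA in 34 of 82 young cells, and the ages were in separate sets of wells.

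**Figure D2:**
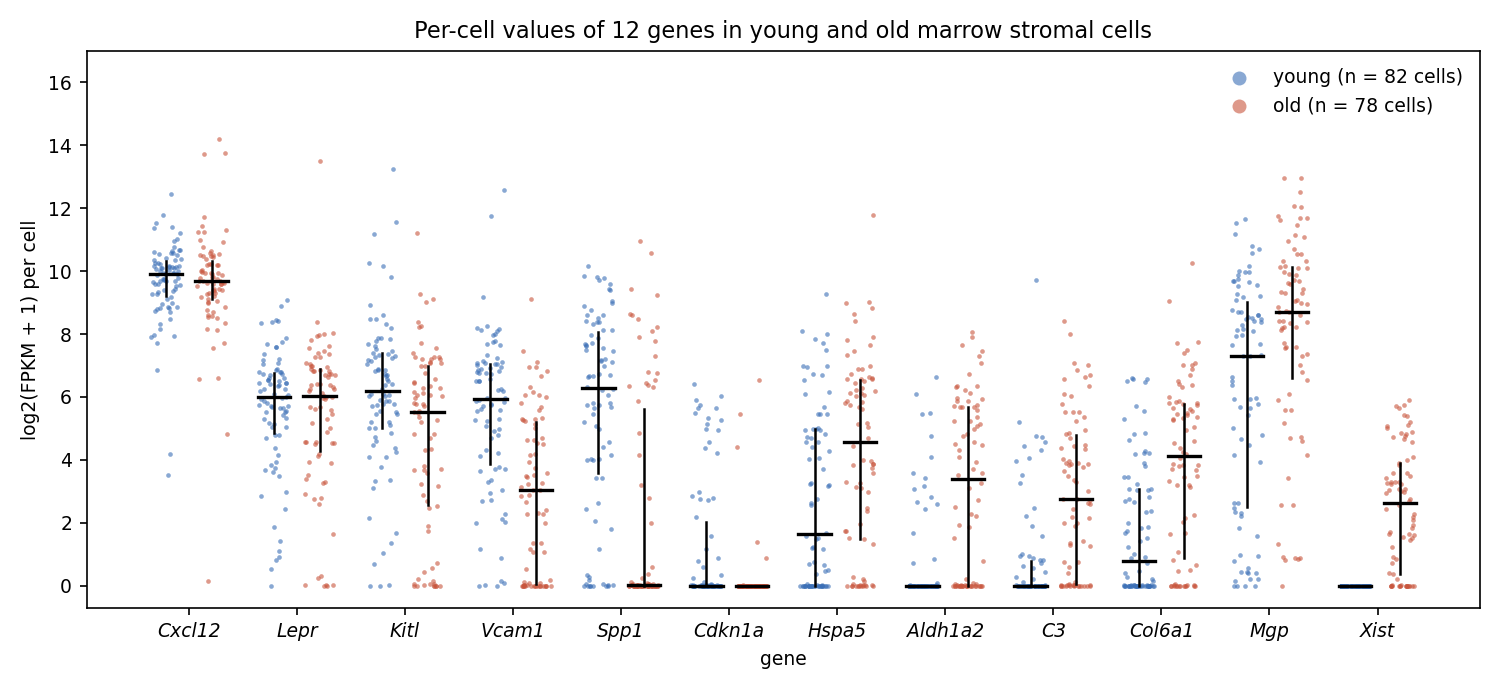
Values of log2(FPKM + 1) per cell for 12 genes, chosen after their values were seen, in 82 young (blue) and 78 old (red) cells. Each point is 1 cell, and the black bars give the median and the quartiles over cells. Cxcl12 and Lepr overlapped between the ages, Spp1 was listed in 82.9% of young and 32.1% of old cells, and Xist in 0 young and 54 old cells.

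Cells of the same age resembled each other about as much as cells of different ages. The median Spearman correlation between pairs of cells, taken across 1376 genes with a mean of 10 FPKM or more, was 0.291 within young cells (quartiles 0.232 and 0.337), 0.273 within old cells (0.214 and 0.324) and 0.261 between the ages (0.204 and 0.311). Genes are not independent replicates, and pairs share cells. The median ratio of the squared coefficient of variation, old over young, was 1.01. It was under 1 in 5 of 6 alternatives and 0.496 over genes with a mean of 100 FPKM or more. With the cells of fewest genes left out, the old minus young difference in median correlation turned from -0.018 to 0.0046.

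Clustering gave 2 clusters whose median numbers of detected genes differed, with overlap between their cells. The number of clusters was taken from 2 to 6, so an undivided set of cells could not be returned. Nearly all cells of summed FPKM over 3 times the median lay in cluster 2. Cluster 1 held 73 cells with a median of 1368 genes (quartiles 1242 and 1581), and cluster 2 held 87 cells with 671 (448.5 and 1064). Cluster 2 held 41 of 82 young cells (50%, interval 38.7 to 61.3) and 46 of 78 old cells (59%, interval 47.3 to 70.0). The leading genes of cluster 1 were Lrrc58, Uqcr11, Foxn3, Naca, Atp6v0e, Dcn and the joint rows of Zbtb20 with BC002163, Ptp4a1 with Gm13363, Rpl12 with Snora65 and Ang with Rnase4, and those of cluster 2 were Klk14, Ctcfl, Rn45s, Col1a2, Canx, S100a11, Lars2, Ddx17, Ebf1 and Rps29. None of these was among the markers fixed beforehand for naming clusters, so neither cluster was named. Dcn belongs to the wider fibroblast list and Ebf1 to the list of marrow stromal transcription factors. For all leading genes of cluster 2 but Rn45s and Lars2, 1 cell held over 50% of the summed FPKM. It ran from 52.9% for Rps29 to 95.2% for Canx, with 91.2% for Klk14. Among the leading genes of cluster 1 this was so only for Lrrc58 (81.2%). In cluster 2, 8 of the 10 leading genes, all but Klk14 and Rn45s, were listed in a smaller share of its cells than of cluster 1. Cxcl12 was listed in 98.6% of cluster 1 and 100% of cluster 2. Lepr was listed in 95.9% and 90.8%, Adipoq in 97.3% and 86.2%, and Kitl in 95.9% and 80.5%.

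**Figure D3:**
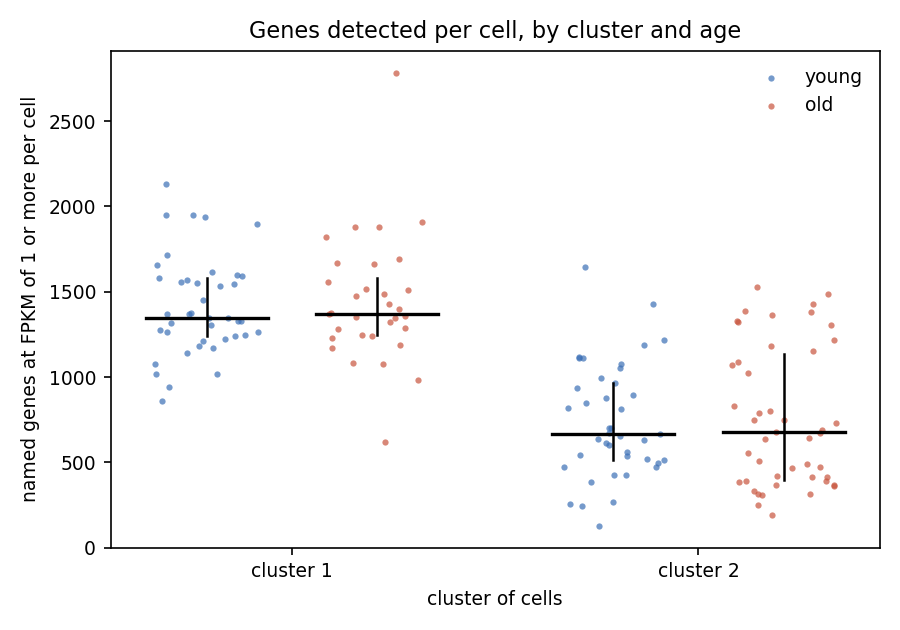
Number of named genes at an FPKM of 1 or more in each cell (linear axis), by cluster and age. Each point is 1 cell, and black bars give the median and quartiles. Cluster 2 had a median of 671 genes and cluster 1 of 1368, and both ages were found in each cluster.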

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

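The trimmed means, the sets of cells by gene number and the difference of mean log2 in all cells were fixed before the data were examined, mean log2 in sets of cells was not, and the use of each as a test of an explanation was chosen after the results were seen, as was the comparison of limits for Xist and Y-linked RNA. Rows with no gene name lie outside every comparison, and they carried a median of 47.2% of the summed FPKM of young cells and 43.8% of that of old cells. What these rows are was not analysed here. No group had 4 to 10 samples, so no sample was set against the rest of its group.

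Xist was listed in old cells and Y-linked RNA in young cells. Estimates that failed equally often at both ages are argued against: the upper exact limit for Xist in young cells was 4.40%, below the lower limit of 57.8% in old cells. Exchanged cells were not tested, and 72 cells listed neither kind of RNA. Xist was in 54 of 78 old and 0 of 82 young cells, and Y-linked RNA in 34 young and 0 old cells. No cell had both. Where sex-linked RNA was listed, it was thus that of female cells in the old and of male cells in the young group. Mice of different sex at the 2 ages would give this. Mice of the same sex at both ages are argued against. For Y-linked RNA the lower exact limit in young cells was 30.7%, above the upper limit of 4.62% in old cells. The limits for Xist lay apart in the opposite direction. The labels give no sex, however, and no value apart from these sex-linked genes bears on it.

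The unfolded protein response list was higher in old cells. Single cells of extreme FPKM are argued against, because the median log2 ratio of means without the highest and lowest 5% of cells was 0.66, at the 99.6th percentile of random lists. A difference in genes detected per cell stays open: the list stood at 1.00 and outside the random range among cells within the interquartile range of genes detected, but at 0.70 and just inside it with the cells of fewest genes left out. By the difference of mean log2 it lay outside in both sets of cells, at 0.40 (99.6th percentile) and 0.46 (99.99th), above the 0.27 of all cells. These 4 values come from the same genes in overlapping sets of the same cells, so they are not separate evidence. Mean log2 in these sets was also chosen after seeing the data, so the values do not decide that explanation. A general stress response to sorting and capture stays open too, because the measures differ: the heat shock chaperones had a median ratio of -0.74 and lay inside the random range, but lay below it by the difference of mean log2 (-0.22, 0.63th percentile). They lay below it in 4 of 17 settings and above it in 0. The immediate early genes, which were not part of this check, had a median ratio of 0.22 (68.6th percentile). They lay outside the random range in 0 of 17 settings. More old than young cells also held 3 or more fibroblast members (38.5% and 22%), which was not tested as an explanation. Age, which the design names, was not tested, because age, sex-linked RNA and the set of wells cannot be told apart with 1 sample per age.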

How the results depend on the processing

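Alternatives that used mean log2 in a set of cells, left out cells of extreme summed FPKM or took the highest of rows that share a name were chosen after seeing the data. So was the choice of the p53 and unfolded protein response lists for separate mention. With no replicates, a share counts as moved outside its exact interval, a list where it enters or leaves the random range, and other values past 1.5 times. No paired analysis was possible because the cell numbers are only names and no result comes from a test. The depth per cell is unknown, so its effect was not measured. The cause of the changes below was not tested.

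Genes detected per cell had medians of 2160.5 in young and 2019 in old cells at any FPKM above 0, which turned the order of the ages. At any FPKM above 0, Lepr was in 98.8% of young and 97.4% of old cells, Cxcl12 in 100% of old cells, Kitl in 98.8% and 91.0%, and Cdkn1a in 50% of young cells. Within the interquartile range of genes detected, Lepr was in 100% of young cells, Kitl in 89.2% and Adipoq in 94.6% of old cells, and with the cells of fewest genes left out these were 100%, 91.4% and 94.8%.

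The unfolded protein response stood above the random lists in 16 of 17 settings, with medians from 0.27 to 1.38, and not by the ratio of means with the cells of fewest genes left out (0.70, 97.4th percentile), where by mean log2 it stood at 0.46 (99.99th). The p53 targets stood at 1.09 within the interquartile range of genes detected. That was the 1 setting of 17 in which they stood apart. Of the 27 lists, 14 stood apart in no setting. At a mean of 10 FPKM or more only 18 of them were placed among random lists. Collagens and matrix stood high in 6 of 17, fibroblast genes in 5, ribosomal proteins in 4 and oxidative phosphorylation in 3, while cell cycle inhibitors and quiescence stood low in 6, the IGF axis in 5 and heat shock chaperones in 4. Adipogenic genes stood high in 1 setting and low in 1. Senescence and secreted factors stood low in 1, as did marrow stromal transcription factors. Counting each list with 5 or more measured members in a setting, which can differ from the 27, lists above and below the random range, 1 and 1 in the main setting, were 3 and 3 after rescaling (the pericyte and smooth muscle list, outside the 27, among the low ones), 2 and 1 with a pseudocount of 0.1, 2 and 2 with a pseudocount of 5, 3 and 4 by the difference of mean log2, 3 and 3 by trimmed means, 3 and 2 without a filter on the mean, and 1 and 0 at a mean of 10 FPKM or more. They were 2 and 1 in cells inside the gate by RNA, 2 and 1 within the interquartile range, 3 and 1 with the cells of fewest genes left out, and 2 and 2 without cells of extreme sums. By mean log2 in these 4 sets of cells they were 2 and 4, 2 and 3, 3 and 2, and 1 and 4.

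Of the 24 genes ranked by the ratio of means, 7 changed sign in some setting, and of the 24 ranked by the difference of mean log2, 0 did. The latter were picked for large differences of mean log2 in these same cells, and several settings use that measure. A constant sign was thus favoured by the choice of genes. Within the interquartile range, Ltbp1 stood at 0.047, Asph at 2.29, Atp5g1 at -1.06, Sdc4 at -0.016 and Snrnp70 at -0.36, and by mean log2 there Asph stood at 0.24, Atp5g1 at -0.39 and Snrnp70 at -0.14. With the cells of fewest genes left out Asph stood at 0.93 and Snrnp70 at -0.16. Asph was 0.36 by trimmed means and 1.00 without cells of extreme sums, where Fbln1 was -0.20 and Ccar1 8.06e-05 by mean log2. Fbln1 was -0.14 after rescaling.

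The old minus young difference in median correlation between cells was -0.018, and it was -0.0088 over genes with a mean of 1 FPKM or more and 0.0046 with the cells of fewest genes left out. The ratio of the squared coefficient of variation fell under 1 in most alternatives: 0.992 and 0.496 over genes with a mean of at least 1 and 100 FPKM, 0.984 inside the gate by RNA, 0.989 within the interquartile range and 0.941 with the cells of fewest genes left out, against 1.18 without cells of extreme sums. Clustering gave 2 clusters with 500 or 2000 genes, after rescaling, and with genes centred within each age.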

Other observations

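Members of the lists that the text has not yet named are given here, picked after their values were seen. Sfrp2, a secreted Wnt antagonist, was listed in 1 young cell and 17 old cells (21.8%, interval 13.2 to 32.6). Fabp4, a fatty acid carrier of adipocytes, was listed in 9 young and 0 old cells. Ctsl, a lysosomal protease, was listed in 63.4% of young and 43.6% of old cells, and Cd63, a lysosomal membrane protein, in 73.2% and 50%. Igfbp5, a binding protein of insulin-like growth factors, was listed in 98.8% and 100% of cells with mean log2(FPKM + 1) of 7.15 and 8.44.

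Some mean FPKM differed between the ages in a way that the share of cells did not follow. Ebf1, a transcription factor of marrow stroma, had a mean of 136 FPKM in young and 746 in old cells, but was listed in 82.9% of young and 65.4% of old cells, and 1 cell held 81.3% of its FPKM. Igfbp7 had means of 1260 and 47.4 FPKM and was listed in 59.8% and 60.3% of cells, with 93.6% of its FPKM in 1 cell. Ifit3, an interferon-induced gene, had means of 2.27 and 1913 FPKM, was listed in 7 young and 3 old cells, and had 99.9% of its FPKM in 1 cell. In the clusters, Pigr was listed in 2.74% of cluster 1 and 43.7% of cluster 2, and Klk14 in 31.5% and 54%.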
